A study of Mus musculus with 13 samples.

How the data were processed

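Whole tumour-draining lymph nodes and whole B16F10 tumours were profiled by bulk RNA sequencing. The comparison of tumour with node and the tests of gene position and pigment transcripts were chosen after the data were seen. Per the labels' protocols, female mice received 5 doses of tamoxifen at 0.1 mg per gram of body weight at 6 to 8 weeks of age. After 9 days without tamoxifen, 200000 tumour cells in matrigel were injected intradermally at up to 11 weeks of age. Only RNA with an integrity number over 9 was sequenced, on a NovaSeq instrument, and all samples carry batch 1 in the labels. The protocol names both poly(A) selection and ribosomal RNA depletion without saying which was used. The genotype of the control mice is given as wild type in one label and as heterozygous floxed in the design text, so they are called Foxp3Ctrl here.

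The deposited values are whole-number counts of reads per gene, not normalized, with one table for nodes and one for tumours. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2, with the build GRCm38. The gene annotation and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes may not be separable. The authors' tables list 49315 gene identifiers, of which 48970 matched the GENCODE M21 annotation of GRCm38, the source of the symbols, gene types and positions.

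The labels describe 13 samples. Counts from 9 libraries were used, namely 3 Foxp3Ctrl nodes, 3 Foxp3ΔJag1 nodes and 3 Foxp3Ctrl tumours. A further 3 columns of the tumour table carry names that match no sample in the labels and were not used in any step. The 4 Foxp3ΔJag1 tumours were therefore not analysed here, and neither the genotype comparison in tumour nor the genotype by tissue interaction was run. Total counts were between 33157236 and 44540888 in nodes and between 32117478 and 40968494 in tumours. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 18.82 and 83.56, so none was treated as a repeat of another. CPM values in the text use the total counts of each library without normalization factors, and means are given with the SD over libraries. Intervals and floors cover counting error only.

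Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter, robust dispersion estimates and Benjamini-Hochberg adjustment over all genes tested, at an FDR of 0.05. The 6 nodes were fitted alone for the genotype comparison. The standard error of a log2 fold change was taken from the coefficient and its F statistic. For a gene with no count in a group, the fold was computed as a lower bound against 3 counts over the group's summed libraries. A total of 31 gene lists of pathways and cell type markers was fixed before the data were examined, and lists with at least 5 measured genes were tested with camera of limma 3.58.1, 2-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with the correlation estimated from the data.

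The rule for named genes was also fixed before the data were examined. It took Jag1 and Foxp3, then the 10 called genes with the largest rise and the 10 with the largest fall whose groups did not overlap, leaving out predicted-gene names, or, where fewer than 5 passed in a direction, the 5 with the smallest p. It added the 3 members with the smallest p of each called list and of the Notch ligand, Notch target, lymphatic endothelial, Treg and cytotoxic lymphocyte lists. Lists of tissues outside the node were summarised as medians per library with their 2 most abundant members. The comparison of tumour with node in the 3 control mice, its rule (5 protein-coding genes with the smallest p per direction and 2 per list) and its alternatives were chosen after the data were seen. It used the same test without a block. The library names give the node and the tumour the same mouse code, and the deviations of same-mouse libraries from their group means correlated at -0.083, 0.127 and -0.003.

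Alternatives were DESeq2 size factors, library size only, DESeq2 1.42.0, limma-voom, voomWithQualityWeights, no filter on low counts, a CPM of at least 1 in at least 3 libraries, non-robust dispersion, the replicate number as a block, a joint fit of the 9 libraries, other thresholds and leaving out each replicate. The tests were also run on simulated counts drawn from the real means, library sizes and dispersions, with 200 changed genes. For the node comparison (18440 genes), 60 of 100 genes changed 2-fold and 88 of 100 changed 4-fold were called, with 15 false calls among 163. For the tissue comparison (18566 genes) these were 49 and 79 of 100, with 9 false calls among 137. All 4 simulated lists of 20 genes raised 1.5-fold were called at the preset correlation in both comparisons. With an estimated correlation 4 were called in the node comparison and 3 in the tissue comparison. The simulated genes were drawn independently of each other, so these results do not cover lists of correlated genes. The tissue simulation also changed far fewer genes than the 13583 called in the real comparison, so it does not cover that setting. Tables were joined with pandas 2.3.3 and plots drawn with matplotlib 3.10.9.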

Results

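Bulk RNA sequencing was available for whole tumour-draining lymph nodes (tdLN) and whole tumours of female mice carrying B16F10, a pigmented mouse melanoma line, injected into the skin of the flank. Mice called Foxp3ΔJag1 carried a tamoxifen-inducible Cre recombinase driven by Foxp3, the lineage factor of regulatory T cells (Tregs), together with floxed Jag1, which encodes the Notch ligand Jagged-1. Their controls are called Foxp3Ctrl, as in the labels, which do not settle the control genotype. The libraries analysed were 3 Foxp3Ctrl tdLN, 3 Foxp3ΔJag1 tdLN and 3 Foxp3Ctrl tumours, the tumours coming, by their library names, from the same 3 mice as the control nodes. Total counts ranged from 32117478 to 44540888 per library. The comparison of tumour with node and the genes said below to be singled out were chosen after the data were seen. The edgeR p-values measure the spread between these animals. The camera p-values set the genes of a list against the other genes, and those of gene position count genes. Neither kind measures the spread between animals alone. All positions are on GRCm38.

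The first comparison asked how the draining node differed between Foxp3ΔJag1 and Foxp3Ctrl mice, the setting in which the series title places lymphatic remodelling by Jagged-1-positive Tregs. The targeted gene, Jag1 (chromosome 2, 137081456 to 137116644), was at 23.2 ± 1.21 CPM in Foxp3Ctrl and 24.1 ± 3.58 CPM in Foxp3ΔJag1 nodes (SD, n = 3 each). Its log2 fold change was 0.03 ± 0.11 (SE) with an edgeR adjusted p of 0.984, so that a loss of Jag1 was not detectable in whole nodes, of which Foxp3-expressing cells are one part. The counts are summed per gene, so reads from the floxed part of Jag1 alone could not be examined. Foxp3 was at 16.03 ± 3.34 CPM in Foxp3Ctrl and 19.7 ± 3.53 CPM in Foxp3ΔJag1 nodes (SD, n = 3 each), with a log2 fold change of 0.28 ± 0.18 (SE) and an edgeR adjusted p of 0.953.

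Of 18440 genes tested with edgeR, 6 rose and 1 fell in Foxp3ΔJag1 nodes, each by at least 2-fold. The one that fell was Rab6b, a small GTPase of Golgi transport (chromosome 9, 103111787 to 103185276), from 32.3 ± 9.02 to 2.54 ± 0.578 CPM (SD, n = 3 each; log2 fold change -3.69 ± 0.24 SE, edgeR adjusted p = 0.00189). Zfp990, a zinc finger gene on chromosome 4 (145510759 to 145539188), rose from 0.135 ± 0.0809 to 29.0 ± 1.97 CPM (SD, n = 3 each; log2 fold change 7.73 ± 0.26 SE, edgeR adjusted p = 5.86e-06). Sycp1, a component of the synaptonemal complex of meiotic chromosomes (chromosome 3, 102818499 to 102936100), had no count in any Foxp3Ctrl node and 85, 83 and 103 counts in the Foxp3ΔJag1 nodes. Against a floor of 3 counts over the control group this was at least 89-fold higher (edgeR adjusted p = 0.00471), a bound that covers counting error only.

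The other 4 genes that rose carry predicted-gene names and fall outside the rule for named genes, so they were singled out after their values were seen. Gm6472, a transcribed processed pseudogene on the X chromosome (152909505 to 152910155), rose from 5.56 ± 0.603 to 50.9 ± 1.46 CPM (SD, n = 3 each; edgeR adjusted p = 4.96e-06). Gm5801, a processed pseudogene on chromosome 14 (56010536 to 56011315), rose from 0.19 ± 0.0429 to 3.82 ± 1.25 CPM (edgeR adjusted p = 0.00653). Gm15056 on chromosome 8 (20900606 to 20902627) rose from 1.18 ± 0.266 to 4.6 ± 0.692 CPM, and Gm21411 on chromosome 4 (146892406 to 146909590) had no count in Foxp3Ctrl nodes and 28, 27 and 32 counts in Foxp3ΔJag1 nodes, at least 28-fold above the same floor. Both had an edgeR adjusted p of 0.0481, and both calls were lost under several alternative settings. Pseudogenes and zinc finger clusters have near-identical copies, and the counts of such genes are uncertain where reads could be assigned to either copy.

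Among the genes with the smallest p that did not pass, Tnfrsf14, a receptor that binds LIGHT and BTLA, was at 37.5 ± 7.99 CPM in Foxp3Ctrl and 66.8 ± 0.287 CPM in Foxp3ΔJag1 nodes (SD, n = 3 each; edgeR adjusted p = 0.174). Pink1, a mitochondrial kinase, was at 92.4 ± 15.5 and 59.6 ± 0.953 CPM (edgeR adjusted p = 0.53). The zinc finger genes Zfp534 and Zfp985 had log2 fold changes of 4.30 and 1.70 with edgeR adjusted p of 0.165 and 0.258, and Unc5cl had -0.86 with 0.203. The immunoglobulin segments Ighv1-69 and Ighv9-4 had log2 fold changes of -1.72 and -2.03 (edgeR adjusted p = 0.166 and 0.53), and their counts share reads with related segments. Tnfrsf14 (154921933 to 154928563), Pink1 (138313409 to 138326307), Zfp534 (147673502 to 147702553) and Zfp985 (147553277 to 147585198) lie on the distal part of chromosome 4, as do Zfp990 and Gm21411.

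**Figure D1:**
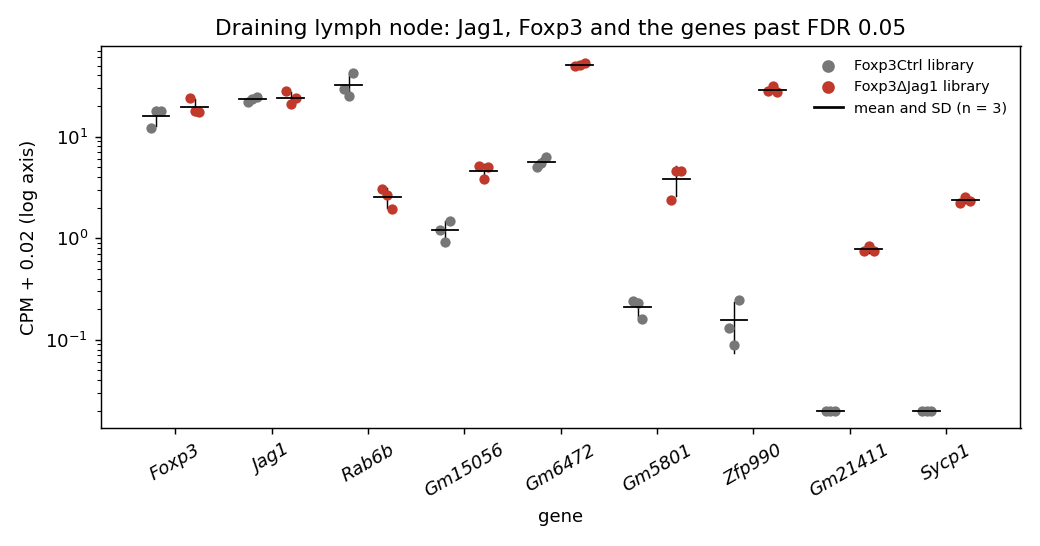
CPM of Jag1, Foxp3 and the 7 genes past an FDR of 0.05 in the 3 Foxp3Ctrl (grey) and 3 Foxp3ΔJag1 (red) draining nodes, on a log axis after adding 0.02; points are libraries, bars the mean and SD. Rab6b sits lower in all Foxp3ΔJag1 nodes, the other 6 called genes sit higher, and the groups overlap for Jag1 and Foxp3.

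**Figure D2:**
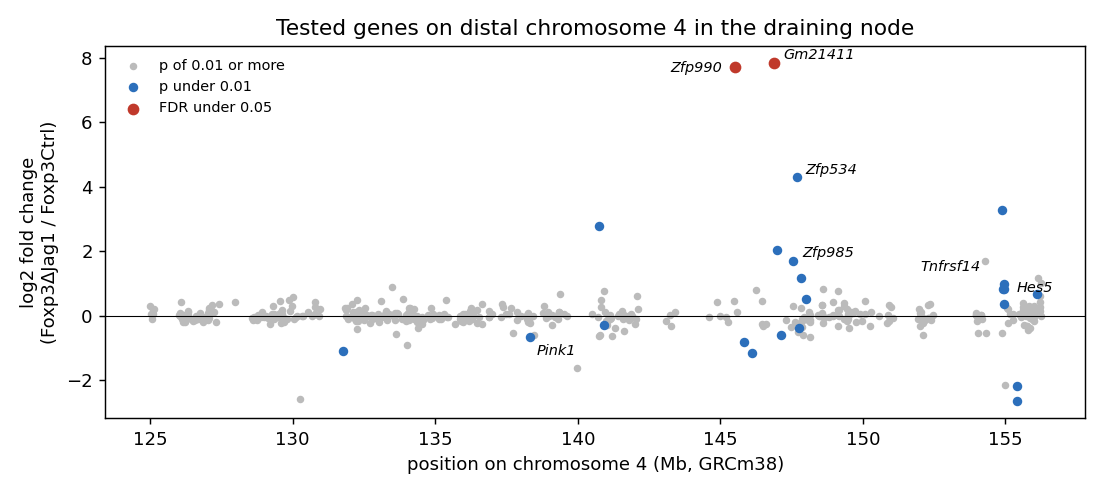
Log2 fold change (Foxp3ΔJag1 over Foxp3Ctrl) of the tested genes on distal chromosome 4 by position in Mb; grey points have a p of 0.01 or more, blue points a p under 0.01 and red points an FDR under 0.05. Zfp990 and Gm21411 are the genes past the threshold there, and the height of Gm21411, with no count in Foxp3Ctrl nodes, depends on the fit.

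Over all genes, 581 (3.151%) had an unadjusted p under 0.05, against 922 expected by chance, and 1345 (7.29%) had groups that did not overlap, against 10% by chance. The count of calls was 44 with DESeq2, 14 with limma voomWithQualityWeights and 16 with no filter on low counts, and all 7 genes were among each of these. Without Foxp3Ctrl replicate 3 the count was 21, and without Foxp3ΔJag1 replicate 2 it was 16. Over all alternatives, Gm15056 lost its call under 10, Gm21411 under 8 and Gm5801 under 1.

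The lymphatic endothelial list (19 genes measured) had a mean log2 fold change of -0.18, with 16 genes lower and 3 higher in Foxp3ΔJag1 nodes, and did not pass the limma camera test (adjusted p = 0.119). None of its members passed, over all genes or adjusted over the list alone, with edgeR. Lyve1, a hyaluronan receptor of lymphatic vessels, was at 87.3 ± 54.6 CPM in Foxp3Ctrl and 67.4 ± 4.63 CPM in Foxp3ΔJag1 nodes. Prox1, the transcription factor of lymphatic identity, was at 15.1 ± 6.62 and 11.6 ± 1.41 CPM, and Flt4, the receptor of VEGF-C, at 31.5 ± 20.3 and 24.3 ± 1.38 CPM (SD, n = 3 each). The edgeR adjusted p was 0.956 for Lyve1 and 0.953 for Prox1 and Flt4. These 3 genes were singled out after their values were seen. The members with the smallest p were the mechanosensitive channel gene Piezo2 (log2 fold change -0.67 ± 0.24 SE), Pdpn (-0.31 ± 0.20 SE) and Mmrn1 (-0.86 ± 0.52 SE), each with an edgeR adjusted p of 0.953. The control nodes were spread widely, with Lyve1 at 89.7, 140.6 and 31.5 CPM in replicates 1, 2 and 3. Without Foxp3Ctrl replicate 3 the list mean was -0.49 (camera adjusted p = 1.47e-05), without Foxp3ΔJag1 replicate 1 it was -0.24 (camera adjusted p = 0.047), and without Foxp3Ctrl replicate 2 it was 0.10 (camera adjusted p = 0.434).

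The Treg list (20 genes) had 10 genes higher and 10 lower, a mean log2 fold change of -0.05 and a camera adjusted p of 0.700. Entpd1, which encodes the ectonucleotidase CD39, was at 51.9 ± 8.95 CPM in Foxp3Ctrl and 43.3 ± 1.45 CPM in Foxp3ΔJag1 nodes. Ctla4, an inhibitory receptor, was at 19.4 ± 2.35 and 23.1 ± 3.22 CPM, and the growth factor gene Areg at 0.531 ± 0.495 and 0.22 ± 0.0682 CPM (SD, n = 3 each; edgeR adjusted p = 0.953 for all 3 genes). Without Foxp3ΔJag1 replicate 1 the list mean was -0.13 with a camera adjusted p of 0.0479, and without Foxp3Ctrl replicate 2 or Foxp3ΔJag1 replicate 3 it was just above 0, at 0.01 in each case. The cytotoxic lymphocyte list (19 genes) had a mean of 0.03 and a camera adjusted p of 0.525. Its mean changed sign with single nodes left out, from -0.07 without Foxp3ΔJag1 replicate 1 to 0.13 without Foxp3ΔJag1 replicate 2. The list passed in none of these fits. Eomes, a transcription factor of effector lymphocytes, had a log2 fold change of -0.27 ± 0.09 (SE), the granzyme gene Gzmc 1.12 ± 0.41 and the NKG2D gene Klrk1 0.20 ± 0.10, with an edgeR adjusted p of 0.953 for each.

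Notch ligands and receptors (15 genes) had 9 members higher and 6 lower, with a camera adjusted p of 0.963. Their mean log2 fold change of 0.0019 and the downward direction of the camera test differed in sign. The Fringe gene Mfng, Dll4 and Notch4 had log2 fold changes of 0.10, -0.19 and -0.16, each with an edgeR adjusted p of 0.953. Notch target genes (14) had a mean of -0.03 and a camera adjusted p of 0.636. Leaving out Foxp3Ctrl replicate 2 gave a mean of 0.08 and leaving out Foxp3Ctrl replicate 3 one of -0.10, and the list passed in neither fit. One target, Hes5 (chromosome 4, 154960923 to 154962371), was at 1.45 ± 0.0521 CPM in Foxp3Ctrl and 2.65 ± 0.336 CPM in Foxp3ΔJag1 nodes (SD, n = 3 each), with an edgeR adjusted p of 0.953 over all genes and of 0.0378 adjusted over the list alone. Hes5 lies close to Tnfrsf14 on distal chromosome 4. The targets Hey1 and Efnb2 had log2 fold changes of -0.40 and -0.25, with an edgeR adjusted p of 0.953.

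Of the 31 gene lists tested in the node with limma camera at a preset correlation, 6 fell and 3 rose in Foxp3ΔJag1 nodes, and 0 did so with an estimated correlation. The number at an adjusted p under 0.05 was 9 with DESeq2 size factors and 13 with voom weights. No member of any list passed over all genes in edgeR. Mast cell genes had the smallest p of the lists at the preset correlation (camera adjusted p = 7.78e-08), though not the largest mean change. Their mean log2 fold change was -0.97, with 8 of 8 genes lower and 6 that fell adjusted over the list alone. With an estimated correlation the call was lost (adjusted p = 0.602 with an estimated correlation). The tryptase gene Tpsb2 was at 10.5 ± 3.57 CPM in Foxp3Ctrl and 3.79 ± 0.873 CPM in Foxp3ΔJag1 nodes, the chymase gene Cma1 at 7.51 ± 2.29 and 3.70 ± 1.44 CPM, and the receptor gene Kit at 34.4 ± 3.71 and 28.5 ± 0.0508 CPM (SD, n = 3 each).

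Erythroid genes had a mean log2 fold change of -1.38, with 5 of 5 lower and 5 that fell adjusted over the list alone (camera adjusted p = 5.39e-07). The adjusted p was 0.602 with an estimated correlation. The globin gene Hbb-bs was at 30.4 ± 12.5 CPM in Foxp3Ctrl and 9.58 ± 2.66 CPM in Foxp3ΔJag1 nodes, Hba-a1 at 16.9 ± 7.37 and 5.96 ± 1.21 CPM, and Hbb-bt at 5.14 ± 1.71 and 1.92 ± 0.647 CPM (SD, n = 3 each). Epithelial genes on the mammary list had a mean of -2.90, with 7 of 7 lower and 5 that fell adjusted over the list alone (camera adjusted p = 9.69e-07). Here too the adjusted p was 0.602 with an estimated correlation. The keratin gene Krt18 was at 10.9 ± 12.8 CPM in Foxp3Ctrl and 0.172 ± 0.104 CPM in Foxp3ΔJag1 nodes, Krt19 at 14.5 ± 18.3 and 0.0536 ± 0.0715 CPM, and the epithelial adhesion gene Epcam at 14.4 ± 5.87 and 8.18 ± 1.49 CPM. The control nodes differed among themselves, with Krt19 at 0.523, 7.82 and 35.3 CPM in replicates 1, 2 and 3. The mast cell, erythroid and mammary lists kept a camera adjusted p under 0.05 when any single node library was left out, with means between -1.23 and -0.74, between -1.81 and -1.15 and between -4.08 and -2.09.

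Proliferation genes had a mean log2 fold change of -0.22, with 18 of 18 lower (camera adjusted p = 0.00123), and neutrophil genes a mean of -1.03, with 11 of 14 lower (camera adjusted p = 0.00345). Both lists had an adjusted p of 0.837 with an estimated correlation. Among the proliferation genes, the kinase genes Bub1 and Aurka had log2 fold changes of -0.35 and -0.36 and the cyclin gene Ccnb1 had -0.41. The neutrophil genes Ly6g, Retnlg and Mmp9 had -1.43, -1.31 and -0.41. The proliferation call ended without Foxp3Ctrl replicate 1 or 2 (camera adjusted p = 0.309 and 0.0960), and the neutrophil call without Foxp3Ctrl replicate 2 or Foxp3ΔJag1 replicate 1 (camera adjusted p = 0.220 and 0.170). Without single nodes the proliferation mean lay between -0.08 (without Foxp3Ctrl replicate 1) and -0.42 (without Foxp3Ctrl replicate 3, camera adjusted p = 1.73e-08). The neutrophil mean lay between -0.46 (without Foxp3ΔJag1 replicate 1) and -1.61 (without Foxp3ΔJag1 replicate 3, camera adjusted p = 1.34e-07).

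General T cell genes had a mean log2 fold change of 0.11, with 14 of 16 higher (camera adjusted p = 0.0332), and interferon response genes a mean of 0.38, with 16 of 22 higher (camera adjusted p = 0.0394). The adjusted p was 0.837 for both with an estimated correlation. The cytokine receptor gene Il7r was at 134 ± 14.0 CPM in Foxp3Ctrl and 150 ± 6.33 CPM in Foxp3ΔJag1 nodes (SD, n = 3 each), and Cd3e and Lef1 had log2 fold changes of 0.17 and 0.18. On the interferon list Irf9 had a log2 fold change of 0.28, and the interferon-inducible GTPase gene Iigp1 had -0.18. Leaving out Foxp3Ctrl replicate 2 gave a camera adjusted p of 0.308 for the T cell list and 0.434 for the interferon list. The T cell call also ended without Foxp3Ctrl replicate 1 and without Foxp3ΔJag1 replicates 1 and 3 (camera adjusted p = 0.124, 0.144 and 0.0522), and the interferon call without Foxp3Ctrl replicate 1 and Foxp3ΔJag1 replicate 2 (camera adjusted p = 0.104 and 0.328). The interferon mean was 0.18 without Foxp3Ctrl replicate 2 or Foxp3ΔJag1 replicate 2 and 0.65 without Foxp3Ctrl replicate 3 (camera adjusted p = 0.00354), and the T cell mean lay between 0.05 and 0.18 without Foxp3Ctrl replicates 2 and 3.

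Collagen and matrix genes had a mean log2 fold change of -0.25, with 16 of 18 lower, and skeletal muscle genes a mean of 0.27, with 6 of 6 higher (camera adjusted p = 0.0394 for both). With an estimated correlation the adjusted p was 0.911 and 0.837. The crosslinking enzyme gene Lox had a log2 fold change of -0.93, the proteoglycan gene Dcn -0.35 and Postn -0.29. On the muscle list Eno3, Atp2a1 and Mylpf had 0.18, 0.26 and 0.31. The collagen call ended without Foxp3Ctrl replicate 1, Foxp3Ctrl replicate 2 or Foxp3ΔJag1 replicate 1 (camera adjusted p = 0.467, 0.783 and 0.359). Its mean lay between -0.04 (without Foxp3Ctrl replicate 2) and -0.57 (without Foxp3Ctrl replicate 3, camera adjusted p = 2.78e-07). The muscle call ended without Foxp3Ctrl replicate 2 or 3 and without Foxp3ΔJag1 replicate 2 or 3, where the camera adjusted p lay between 0.0540 and 0.434, and its mean between 0.08 and 0.32 without single nodes.

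**Figure D3:**
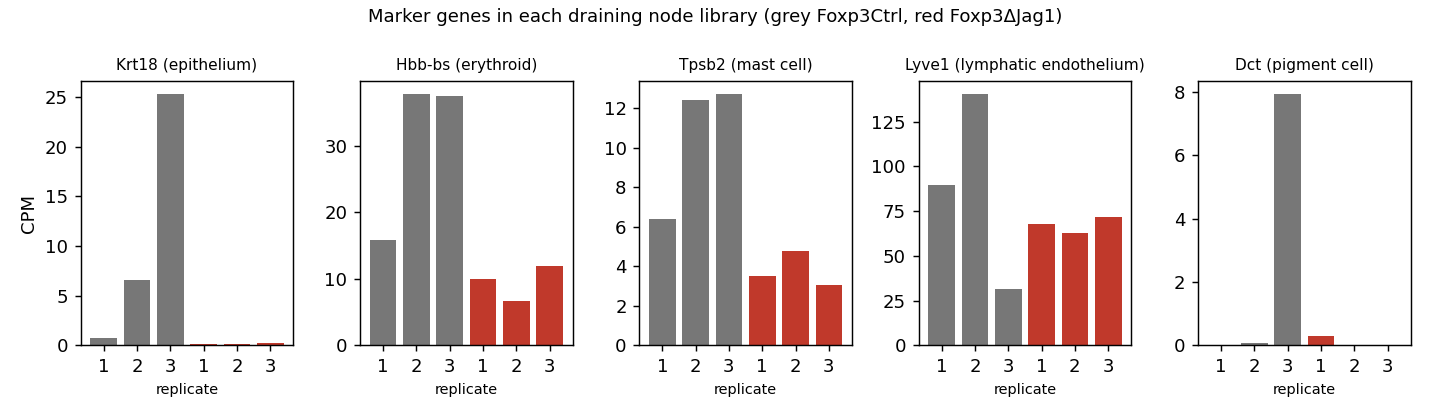
CPM of 5 marker genes in each draining node library, with Foxp3Ctrl replicates in grey and Foxp3ΔJag1 replicates in red; each bar is 1 library and each panel has its own axis from 0. Krt18 and Dct are highest in Foxp3Ctrl replicate 3, in which Lyve1 is lowest (31.5 CPM), and Hbb-bs and Tpsb2 are lower in all Foxp3ΔJag1 nodes.

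Markers of other tissues varied between single nodes. The median over the adipocyte list was 6.27 CPM in Foxp3Ctrl replicate 3 and 9.63 CPM in Foxp3ΔJag1 replicate 1, and between 0.303 and 0.639 CPM in the other nodes. Of its abundant members, Lpl followed the median, at 122 and 111 CPM in these nodes and between 43.9 and 86.5 CPM in the others. Pnpla2 did not, at 81.0 CPM in Foxp3Ctrl replicate 3, 97.5 CPM in Foxp3ΔJag1 replicate 1 and 103 CPM in Foxp3Ctrl replicate 2. The keratinocyte list had a median of 2.47 CPM in Foxp3Ctrl replicate 3 and of 0.871 CPM in Foxp3Ctrl replicate 2, against 0.207 to 0.225 CPM in the other nodes. Its abundant members did not follow the median, with Sfn at 37.2 CPM in Foxp3Ctrl replicate 3 and between 35.7 and 44.2 CPM in the other nodes, and Sbsn at 4.68 CPM there and 4.71 CPM in Foxp3ΔJag1 replicate 1. The mammary list had medians of 0.275, 0.917 and 2.43 CPM in Foxp3Ctrl replicates 1, 2 and 3, and of 0.039, 0.0452 and 0.191 CPM in the Foxp3ΔJag1 nodes. The erythroid list had medians of 2.34, 5.94 and 6.20 CPM in Foxp3Ctrl and of 1.69, 1.42 and 2.45 CPM in Foxp3ΔJag1 nodes. The muscle list had medians between 0.174 and 0.273 CPM in all 6 nodes, with Eno3 at 31.2 to 43.7 CPM. The melanocyte and melanoma list had a median of 2.19 CPM in Foxp3Ctrl replicate 3 and of 0.313 CPM or less in the other nodes, with Mitf between 5.78 and 10.3 CPM and Gpnmb between 4.22 and 12.7 CPM.

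Among the lists that did not pass in the node, blood endothelium (18 genes), antigen presentation (17), B cells (12) and dendritic cells (15) had mean log2 fold changes of -0.04, 0.05, -0.01 and -0.05, with camera adjusted p of 0.351, 0.136, 0.865 and 0.796. Antigen presentation passed without Foxp3Ctrl replicate 1 (mean 0.08, camera adjusted p = 0.0444). The germinal centre list (12 genes) had a mean of 0.04 and a camera test pointing downwards (adjusted p = 0.865), but without Foxp3ΔJag1 replicate 3 the mean was -0.20 (camera adjusted p = 0.00785) and without Foxp3ΔJag1 replicate 1 it was 0.19. Macrophage and monocyte genes (18) and plasma cell genes (14) had means of -0.09 and -0.15, with camera adjusted p of 0.636 and 0.0813. Without Foxp3Ctrl replicate 3 both lists passed, with means of -0.26 and -0.63 (camera adjusted p = 0.0136 and 1.28e-07). The plasma cell list also passed with voom weights (camera adjusted p = 0.0377) and without Foxp3ΔJag1 replicate 1 (0.0388), and its mean was 0.05 and 0.12 without Foxp3Ctrl replicates 1 and 2.

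The second comparison set the tumours of the 3 control mice against their own draining nodes, as a description of both tissues, and was chosen after the data were seen. Pigment cell genes, those of the cell cycle and those of hypoxia and glycolysis were higher in the tumour, and those of B cells, T cells, Tregs and dendritic cells were lower. These list calls were lost with an estimated correlation, with adjusted p = 0.636 with an estimated correlation for cell cycle and hypoxia genes and adjusted p = 0.575 with an estimated correlation for the other lists named. Of 18566 genes tested with edgeR, 6611 were higher and 6972 lower in the tumour, and 8992 differed by at least 2-fold. Of these genes, 14466 (77.92%) had groups that did not overlap, against 10% by chance. Without normalization factors the median log2 fold change of all genes was -0.11, against -0.05 with them, and the fold changes below stand relative to the latter.

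All 14 melanocyte and melanoma genes were higher in the tumour, over all genes and adjusted over the list alone, with a mean log2 fold change of 10.19 (camera adjusted p = 1.08e-06, and adjusted p = 0.575 with an estimated correlation). Tyr, the tyrosinase gene, was at 0.493 ± 0.142 CPM in nodes and 664 ± 205 CPM in tumours, and Mitf, the lineage transcription factor, at 8.21 ± 2.28 and 691 ± 106 CPM (SD, n = 3 each; log2 fold changes 10.43 ± 0.35 and 6.45 ± 0.27 SE, edgeR adjusted p = 4.07e-07 and 8.73e-07). The genes with the smallest p among those higher in the tumour were the carbonic anhydrase gene Car14 (log2 fold change 11.22 ± 0.19 SE), Fndc3c1 (11.25 ± 0.22), Shc4 (8.64 ± 0.17), Capn6 (9.18 ± 0.19) and the transcription factor gene Sox11 (8.06 ± 0.17). Car14 had an edgeR adjusted p of 7.64e-08 and the other 4 genes one of 8.24e-08.

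All 18 proliferation genes were higher in the tumour (mean log2 fold change 1.65, camera adjusted p = 5.06e-05), among them Foxm1, a transcription factor of the cell cycle, at 28.3 ± 4.16 CPM in nodes and 134 ± 11.6 CPM in tumours, and the replication licensing gene Mcm2 at 97.2 ± 10.9 and 423 ± 56.9 CPM (SD, n = 3 each). Of 17 hypoxia and glycolysis genes, 14 were higher and 3 did not pass (mean 2.56, camera adjusted p = 5.06e-05). The glycolytic genes Pgk1 and Aldoa had log2 fold changes of 3.96 ± 0.21 and 2.74 ± 0.16 (SE). Both lists had an adjusted p of 0.636 with an estimated correlation. Of 18 collagen and matrix genes, 14 were higher, 1 was lower and 3 did not pass (mean 1.55, camera adjusted p = 0.0136, and adjusted p = 0.734 with an estimated correlation). Col6a3 was at 32.6 ± 7.05 CPM in nodes and 142 ± 66.3 CPM in tumours, and Dcn, the member that was lower, at 223 ± 69.8 and 47.5 ± 18.5 CPM. Each count of members was identical when adjusted over the list alone.

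Lymphocyte genes were lower in the tumour. All 12 B cell genes (mean log2 fold change -9.38, camera adjusted p = 1.08e-06) and all 16 T cell genes (mean -5.23, camera adjusted p = 1.95e-07) passed, and the adjusted p was 0.575 for each list with an estimated correlation. The B cell receptor gene Cd79a was at 780.1 ± 54.3 CPM in nodes and 0.725 ± 0.0203 CPM in tumours, and the kinase gene Blk at 155 ± 4.26 and 0.146 ± 0.0207 CPM (SD, n = 3 each). Blk, Cd79a, Grap (log2 fold change -4.76), Spib (-8.31) and Cxcr5 (-6.81) had the smallest p among genes lower in the tumour, with edgeR adjusted p between 7.00e-08 and 8.24e-08. The T cell signalling genes Cd247 and Lck had log2 fold changes of -5.35 ± 0.14 and -4.74 ± 0.12 (SE). Of 19 Treg genes, 17 were lower and 2 did not pass (mean -2.53, camera adjusted p = 3.53e-05, and adjusted p = 0.575 with an estimated correlation), and Foxp3 was at 16.03 ± 3.34 CPM in nodes and 0.916 ± 0.104 CPM in tumours. Nt5e, the gene of CD73, and the costimulatory receptor gene Icos had log2 fold changes of -3.76 and -4.92. Of 19 cytotoxic lymphocyte genes, 15 were lower, 2 higher and 2 did not pass (16 lower and 2 higher adjusted over the list alone), with a mean of -2.26 and a camera adjusted p of 0.00139. The adjusted p was 0.636 with an estimated correlation. Cst7 and Eomes had -4.02 and -4.06.

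Of 15 dendritic cell genes, 14 were lower (mean log2 fold change -2.85, camera adjusted p = 9.62e-05), among them Flt3 (-4.66) and the chemokine gene Ccl22 (-4.49), and of 12 germinal centre genes 10 were lower and 2 higher (mean -3.09, camera adjusted p = 0.0106). Both lists had an adjusted p of 0.575 with an estimated correlation. Of 14 plasma cell genes, 12 were lower and 2 higher (mean -5.74, camera adjusted p = 0.00229), with Jchain at 882 ± 398 and 0.654 ± 0.266 CPM and Ighm at 2805 ± 348 and 13.7 ± 2.80 CPM. The adjusted p was 0.636 with an estimated correlation. Of 13 neutrophil genes, 12 were lower (mean -3.99, camera adjusted p = 0.00139, and adjusted p = 0.575 with an estimated correlation), with Cxcr2 at -6.29 and Ngp at 42.7 ± 15.5 CPM in nodes and 0.0104 ± 0.018 CPM in tumours. Of 17 antigen presentation genes, 10 were lower and 7 did not pass (mean -1.35, camera adjusted p = 0.00768, and adjusted p = 0.651 with an estimated correlation), with the MHC class II genes Cd74 and H2-Aa at log2 fold changes of -2.86 and -2.75. These counts of members were identical when adjusted over each list alone.

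Genes of high endothelial venules and of reticular fibroblasts were also lower in the tumour. Of 18 genes of blood endothelium and high endothelial venules, 14 were lower and 4 did not pass (mean log2 fold change -2.85, camera adjusted p = 0.00159), and of 14 reticular fibroblast genes 11 were lower, 1 higher and 2 did not pass (mean -2.71, camera adjusted p = 0.00382). Both lists had an adjusted p of 0.636 with an estimated correlation. Glycam1, a ligand of L-selectin in high endothelial venules, was at 1894 ± 446 CPM in nodes and 0.0104 ± 0.018 CPM in tumours (SD, n = 3 each), and Fut7 had a log2 fold change of -5.14. The survival factor gene Il7 and Tnfsf11, which encodes RANKL, had -4.71 and -4.85. The lymphatic endothelial list (19 genes) had 10 members lower, 3 higher and 6 that did not pass, with a mean of -2.03 that did not pass as a list (camera adjusted p = 0.113) except without replicate 3 (mean -2.24, camera adjusted p = 0.0341). Cldn11 was at 6.88 ± 1.14 CPM in nodes and 0.0259 ± 0.0267 CPM in tumours, and Tbx1 had a log2 fold change of -5.72.

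Notch ligands and receptors were lower in the tumour for 9 of 15 genes and higher for 1 (mean log2 fold change -1.09, camera adjusted p = 0.0471, and adjusted p = 0.651 with an estimated correlation). Without replicate 3 the list did not pass (camera adjusted p = 0.0540). Jag1 was at 23.2 ± 1.21 CPM in nodes and 13.9 ± 2.54 CPM in tumours (SD, n = 3 each; log2 fold change -0.68 ± 0.16 SE, edgeR adjusted p = 0.00439), and Mfng and Notch2 had log2 fold changes of -3.47 and -2.52. Of 14 Notch targets, 8 were lower and 2 higher (mean -1.57), and the list did not pass (camera adjusted p = 0.0603) except without replicate 1 (camera adjusted p = 0.0323). Dtx1 and Cd28 had -7.84 and -5.01. Each count was identical when adjusted over the list alone. In total, 16 of the 31 lists passed at the preset correlation, 4 higher and 12 lower in the tumour, and 0 passed with an estimated correlation.

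**Figure D4:**
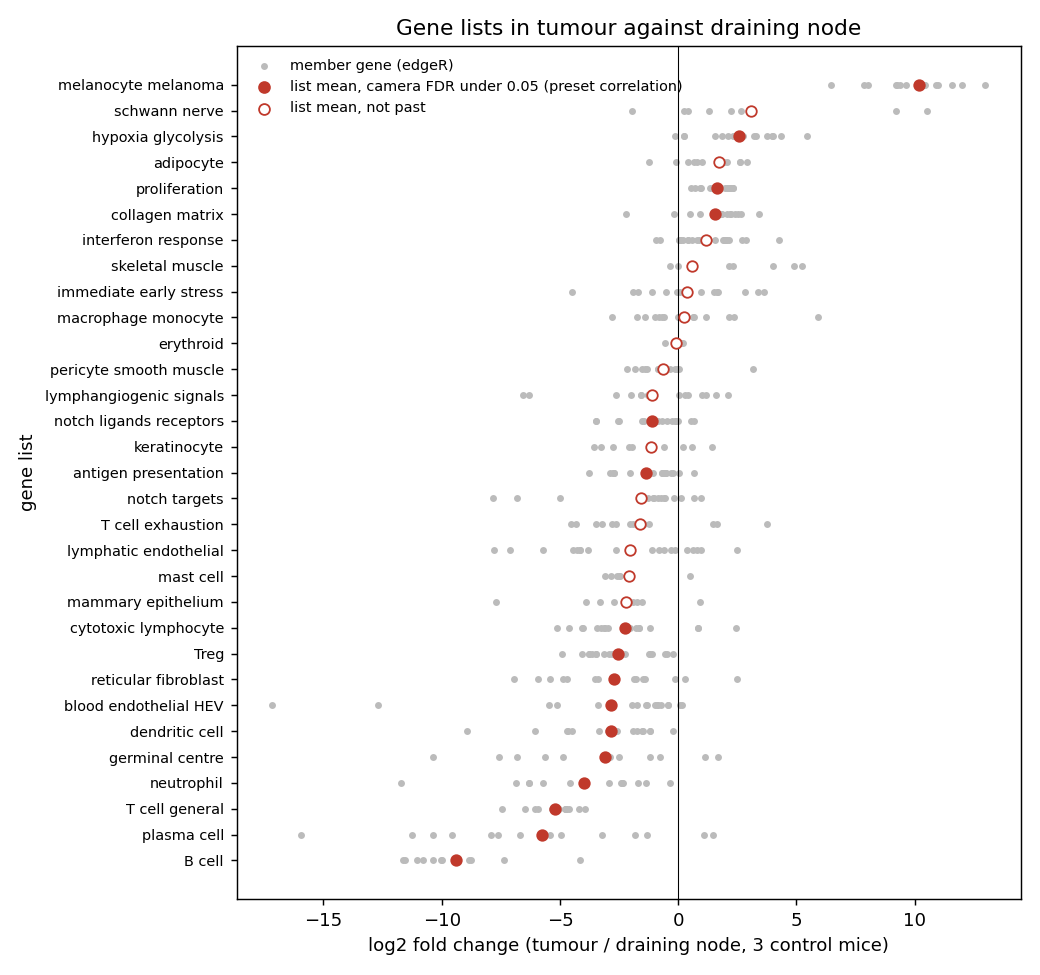
Log2 fold change of tumour against draining node in the 3 control mice for the members of 31 gene lists (grey) and for each list's mean (red, filled where the camera adjusted p was under 0.05 at the preset correlation). The melanocyte list stands highest at 10.19 and the B cell list lowest at -9.38; the folds of genes near 0 in one tissue depend on the fit.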

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

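Of the alternatives below, the joint fit of 9 libraries (planned for 13) and all those of the tissue comparison were chosen after the data were seen. The planned fits of the tumour genotype comparison and of the genotype by tissue interaction were not run, since the Foxp3ΔJag1 tumours were not analysed here. The main count of 7 genes in the node was 44 with the DESeq2 Wald test, 14 with voomWithQualityWeights, 16 with no filter on low counts and between 6 and 21 when single replicates were left out. It was between 5 and 8 with the other scalings, filters, tools and thresholds. Gm6472, Zfp990, Rab6b and Sycp1 passed under all 16 alternatives that retested them, and Gm5801 lost its call with limma-voom. Gm15056 lost its call under 10 of 16 alternatives and Gm21411 under 8 of 15. The cause was not tested.

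The replicate numbers of the 2 groups of nodes come from different mice. The deviations of same-numbered libraries from their group means correlated at -0.165, 0.034 and -0.124. With the replicate block, 11 genes were called, 6 of them among the 7, and 12 lists were called, with plasma cells, pericytes and keratinocytes added to the 9. In the tissue comparison the block of mice changed no list call.

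Jag1 in the node had log2 fold changes between -0.0786 (without Foxp3ΔJag1 replicate 1) and 0.12 without single replicates. Dll4 lay between -0.33 and 0.0035 and Notch4 between -0.24 and 0.0122, both changing sign without Foxp3Ctrl replicate 2. The 9 lists called in the node became 0 with an estimated correlation and between 3 and 14 without single replicates. The lymphatic endothelial list mean lay between -0.49 and 0.10 and the Treg list mean between -0.13 and 0.0094 without single replicates, with the lymphatic list past the threshold without Foxp3Ctrl replicate 3 or Foxp3ΔJag1 replicate 1 and the Treg list without Foxp3ΔJag1 replicate 1 only. The 13583 genes of the tissue comparison became 8992 with an absolute log2 fold change of at least 1, and its 16 lists became 0 with an estimated correlation. At these depths, values under about 0.1 CPM rest on a few counts.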

Other observations

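The tests of gene position and of pigment transcripts in this part were chosen after the results were seen. The test of near-identical copies replaced a first version that used the crowded region itself and was partly circular, and the tests of pigment transcripts were replaced after first versions had been run. In the tumours of the control mice, Schwann cell and nerve genes had 6 of 8 members higher and 1 lower than in the draining nodes (mean log2 fold change 3.10, camera adjusted p = 0.119), and interferon response genes had 12 of 22 higher and 1 lower (mean 1.16, camera adjusted p = 0.0803), or 8 higher and 1 lower adjusted over the list alone. Exhaustion genes had 10 of 13 lower and 3 higher (mean -1.60, camera adjusted p = 0.0587), and mast cell genes 6 of 7 lower (mean -2.09, camera adjusted p = 0.0693). Immediate early and stress genes went both ways, with 7 of 14 higher and 5 lower (camera adjusted p = 0.612), as did macrophage and monocyte genes, with 4 of 18 higher and 4 lower (camera adjusted p = 0.790). None of these lists passed as a list. Lymphangiogenic signals (camera adjusted p = 0.417), pericytes (0.283), keratinocytes (0.417), muscle (0.866), adipocytes (0.417), mammary epithelium (0.226) and erythroid genes (0.988) did not pass either. Leaving out single mice brought several of these lists past the threshold. Without replicate 1 these were mast cells, mammary epithelium and exhaustion (camera adjusted p = 0.00562, 0.0143 and 0.0365), without replicate 2 interferon response (0.0422), and without replicate 3 interferon response, adipocytes, Schwann cells and exhaustion (0.0151, 0.00272, 0.0487 and 0.0447). Exhaustion genes also passed with voom weights (0.0494). Markers of other tissues varied between single tumours as well. The muscle list had medians of 0.213, 0.464 and 21 CPM in tumour replicates 1, 2 and 3, and the adipocyte list of 15.4, 14.4 and 0.825 CPM. The muscle list mean was 2.32 without replicate 1 and -1.23 without replicate 3.

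In the draining nodes, 6 lists that the genotype comparison leaves below the threshold had camera adjusted p of 0.351 (lymphangiogenic signals), 0.0718 (pericytes), 0.700 (reticular fibroblasts), 0.865 (exhaustion), 0.0791 (hypoxia and glycolysis) and 0.0547 (Schwann cells and nerve). Keratinocyte, melanocyte, adipocyte and immediate early lists had 0.0813, 0.324, 0.790 and 0.383. Several of these calls hung on single nodes. The keratinocyte list passed without Foxp3Ctrl replicate 1 (mean -1.67, camera adjusted p = 4.41e-06) and without Foxp3ΔJag1 replicate 1 or 2 (0.00834 and 0.00883), the melanocyte list without Foxp3Ctrl replicate 1 (0.0337) and the adipocyte list without Foxp3ΔJag1 replicate 1 (mean -1.02, 0.00834). Without Foxp3Ctrl replicate 3 the lymphangiogenic, pericyte and hypoxia lists passed (0.0339, 0.00739 and 0.0136), and without Foxp3ΔJag1 replicate 1 the hypoxia and Schwann cell lists did (0.0379 and 0.00852). Pericytes also passed without Foxp3ΔJag1 replicate 2 (0.0233), the pericyte, hypoxia and Schwann cell lists with voom weights (0.0377, 0.0374 and 0.0377), and the Schwann cell list with a CPM of at least 1 in 3 libraries (0.0102). On the melanocyte list, Tyr was at 0.493 ± 0.142 CPM in Foxp3Ctrl and 0.103 ± 0.0887 CPM in Foxp3ΔJag1 nodes (SD, n = 3 each), the 1 member that fell adjusted over the list alone, with an edgeR adjusted p of 0.953 over all genes.

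The 3 nodes of each group allow 10 splits, too few for a share under 0.05. The real split gave 7 genes and the highest of the others 5, so only 1 of the 10 splits, the real one itself, gave as many. For gene lists the real split gave 9 and the highest of the others 12, and 9 of the 10 splits, the real one included, gave as many. A split that set Foxp3Ctrl replicates 1 and 2 with Foxp3ΔJag1 replicate 3 against the other nodes had 2682 genes at an unadjusted p under 0.05, against 581 for the real split. In the tissue comparison the real split gave 13583 genes and the highest of the others 0 (1 of 10 splits as many, the real one itself). It gave 16 lists against 22 (8 of 10 splits as many, the real one included).

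Part of the genes that differed between the nodes of the genotypes was crowded in the genome. Outside immunoglobulin and T cell receptor segments, 105 of 17972 genes had an unadjusted p under 0.01. Crowded regions of chromosomes 4 and 8 held 21 and 6 of them, with the called genes Zfp990, Gm21411 and Gm15056. The other called genes, Rab6b, Sycp1, Gm6472 and Gm5801, lie on other chromosomes. In windows of 50 neighbouring tested genes without immunoglobulin and T cell receptor segments, up to 11 genes had a p under 0.01, on chromosome 4 between 141613376 and 148038821, against a 95th percentile of 4 in 1000 shuffled gene orders (permutation p = 0.000999), and a region of chromosome 8 between 12614277 and 25454704 also exceeded it. Zinc finger, predicted and noncoding models with a p under 0.01 crowded between 130766331 and 156127265 on chromosome 4. They also crowded between 3353415 and 61928028 on chromosome 8. Inside these intervals, chosen by low p and not by the density of such models, 39 of 495 other protein-coding genes (7.88%) had a p under 0.05. Elsewhere these were 354 of 13180 (2.69%; Fisher's exact test, 2-sided, p = 1.07e-08). The difference was therefore not confined to genes with such names. The intervals were drawn from p-values in the same nodes. Fisher's test, like the shuffled gene orders, counts neighbouring genes as independent. The other genes were told apart by name and type only. Reads shared between near-identical copies therefore stay open as a cause. A candidate explanation for the crowding is genetic background that differs between the groups outside the Jag1 locus. Without those gene families the densest window was another one on chromosome 4, between 149979475 and 155466823. It held 5 genes against a 95th percentile of 4 and a highest value of 5 in shuffled orders (permutation p = 0.005). Within 10 Mb of Jag1 the share of genes with a p under 0.05 was 3.68% against 3.02% elsewhere (Fisher's exact test, 2-sided, p = 0.61), which leaves background around Jag1 itself open. An effect of the deletion on these genes, Hes5 and Tnfrsf14 included, stays open and untested, since genotype and background cannot be told apart in 3 nodes against 3.

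Foxp3Ctrl replicate 3 stood apart from the other nodes in pigment cell transcripts, with 282 counts of Dct and 63 of Tyrp1 against at most 11 and 6 in any other node. Pigment cells within the node may be the source, and so may tumour RNA carried between libraries. A set of 19 other genes at 50 CPM or more in the tumour of that mouse and under 0.1 CPM in the other control nodes, Mc1r and Pax3 among them, summed to 97 counts (exact Poisson 95% interval 78.7 to 118), against 89.5 predicted from a Dct share of 0.0903%. In the Foxp3ΔJag1 nodes, which took no part in choosing these genes, the sums were 23, 18 and 30. Carried tumour RNA would give such a sum as well. Of 11 pigment list members with enough predicted counts, 2 lay more than 2-fold off a common tumour share by their whole exact 95% interval. These were Gpnmb and Sox10, too few to exclude carried tumour RNA. The intervals of the other members tested reached within 2-fold, that of Tyrp1 included. Counts of Tyrp1 per count of Dct were 0.223 in the node and 0.554 in the tumour of that mouse. Whether pigment cells in the node would be melanoma cells or melanocytes was not tested, and this node also had the highest keratinocyte median, at 2.47 CPM.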
